A study of Caenorhabditis elegans with 2 samples.

How the data were processed

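Chromatin from whole Caenorhabditis elegans hermaphrodites at the late embryonic stage was immunoprecipitated with an antibody against GFP and sequenced, per the labels. The strain, OP433, carries an integrated transgene, wgIs433, that makes the transcription factor HLH-30 with a GFP-FLAG tag at its C terminus, in an unc-119 mutant background. HLH-30 is a basic helix-loop-helix leucine zipper protein of the TFEB family. The samples form a single group with 2 biological replicates, so the comparisons were between replicates, between peak centres and their own flanks, between peaks and random positions, and between gene lists and all other genes. A control experiment is named in the labels and was not analysed here as a library of its own.

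The deposited files are narrowPeak lists, each in the genome builds ce10 and ce11. For each replicate the authors called peaks and background against a control, per the descriptions deposited with the files. The authors made a pooled list in the same way from both replicates' alignments together, and an optimal list by irreproducible discovery rate (IDR), a method that keeps peaks whose order is shared by replicates. The aligner, the peak caller, its version, its filters and the IDR cut-off are not given in the sources used here. Each peak carries the authors' signal value, made against the control, whose scaling by depth is not given in the sources used here and whose scale differs between lists. The signal was therefore used to describe, rank or filter peaks within a list, and across lists only in a correlation over matched peaks. The authors' −log10 q-value reaches an upper limit at 3.50 in the optimal ce11 list, where 1571 of the 1959 peaks share it, so peaks were not ranked by it. The p-value column of the deposited lists holds -1 throughout, the format's mark for no value. Read totals are not used here, so the depth of each replicate is unknown. The replicate 2 list ends at 30000 peaks in both builds, a round number, whereas the replicate 1 list holds 11695 in ce11 and 11786 in ce10. The ce11 optimal list was the 1959 pooled peaks with the highest signal, 10.4% of the pooled list, with a lowest signal of 47.7. Single peaks in it were thus not each shared by the replicates, and 85 had no summit within 100 bp in the whole replicate 1 list.

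All positions are in ce11 and count from 1, and no coordinate was converted between builds. Summits come from the offset each deposited row gives. Ensembl gene models of WBcel235, the same assembly as ce11, gave 19973 protein-coding genes on the nuclear chromosomes, and the RefSeq sequence of that assembly gave the bases. Summits were matched between lists within 100 bp. Hexamers were searched on both strands within 50 bp of the summit and in windows of equal length centred 500 bp to either side. Centre and flank were compared by a two-sided exact sign test over peaks in which they differed, separately for each flank, keeping the larger p. Hexamers merged with their reverse complements were ranked by a z score of the difference from the flanks, with a pseudocount of 1 in the ratio. The 489 optimal peaks with the highest and the 489 with the lowest signal were compared by a two-sided Fisher's exact test. Distances to gene starts, regions under the summit and distances to noncoding genes were compared with 1000 sets of random positions on the same chromosomes, for which the smallest two-sided permutation p is 0.002. A gene had a peak when a summit lay from 1000 bp upstream to 200 bp downstream of any of its annotated starts. Each of 22 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists, and with 10000 random lists of the same size and the same deciles of upstream intergenic length. Odds ratios were computed with a small constant added to every count, which raises them where few genes of a list have a peak. Of the symbols written for these lists, 7 matched no protein-coding gene by symbol and were left out. The gene tables used here held no synonyms. Of the 7, 4 are older names, of unc-108, rpn-6.1, egl-18 and hsp-90, and were matched in an alternative added after the data were seen. Shares carry exact 95% binomial intervals, which cover counting of peaks or genes only and not differences between embryo collections. Peaks and genes are not biological replicates. The correlation's interval is from 1000 bootstrap draws over peaks.

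The genes named follow a rule set before the data were examined. They are the gene with the nearest annotated start within 2000 bp for the 25 strongest optimal peaks, after keeping the strongest of any summits within 500 bp of each other, then up to 4 members with the strongest peaks of each list, then the nearest gene of the 5 strongest peaks with TCACGTGA, then hlh-30 and unc-119. The groups, tests, lists and most alternatives were also set before the data were examined. Alternatives were each replicate's list alone at the same number of peaks, a stricter list, merged summits, other windows, flanks and gene definitions, and the ce10 lists. The search, ranking, list and matching steps were tested on simulated peaks. In 1959 simulated peaks at random positions with CACGTG planted in some, 100% of the planted peaks were found and CACGTG ranked 1, and without planting the exact sign test gave p = 0.822. The planted word was the one searched for, so this shows only that the search works as written. Of 200 random gene lists tested against the simulated peaks over 19973 genes, 5.50% had an unadjusted p under 0.05. Of simulated summits placed anew, 0.397% matched by chance. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.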

Results

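HLH-30 binding was mapped by chromatin immunoprecipitation of the GFP-tagged protein in late embryos of C. elegans, in 2 biological replicates of the same strain. The replicate lists held 11695 and 30000 peaks in ce11, the list pooled over both held 18832, and the optimal list after IDR held 1959. Peak signals are the authors' own values, with a median of 72.7 in the optimal list. No second condition, stage or strain was part of the series, and unless replicates are named the values below come from the optimal list, which pools both and so has no spread between replicates.

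Of the 25 strongest peaks, 4 had as their nearest gene a member of the list of genes for autophagy, the process that encloses cytoplasm and delivers it to lysosomes, and whether this exceeds chance was not tested. The highest signal, 1042, was at chromosome IV, 2601987 to 2602371, in an intron 1028 bp from the nearest annotated start of epg-9, an autophagy initiation factor. The peak of rank 3, signal 847, was intergenic on IV, 10936018 to 10936361, 295 bp from the start of lgg-2, and that of rank 12, signal 675, was intergenic on II, 6348447 to 6348752, 877 bp from the start of lgg-1. Both genes encode homologues of the autophagosome protein Atg8. Rank 11, signal 686, was intergenic on X, 7334386 to 7334727, 143 bp from the start of epg-7, an autophagy scaffold gene. Among these peaks, 21 had a protein-coding start within 2000 bp. The other genes nearest to these were tasp-1, tos-1, mtm-3, T28F4.1, iff-2, T28B8.1, C18B12.4, ztf-7, psd-1, F56C9.10, gei-4, B0546.4, W03C9.5, F58D5.5, ubc-8, sup-26 and epn-1. Among them mtm-3 encodes a myotubularin-family phosphatase, psd-1 a phosphatidylserine decarboxylase and iff-2 a translation factor of the eIF5A family. Within 50 bp of the summit, 4 of the 25 held CACGTG, 8 held CATGTG and 10 held GAGAGA.

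The replicates shared most of their strongest peaks. Of the 1959 highest-signal peaks of replicate 1, 1322 or 67.5% (exact 95% interval 65.4 to 69.6%) had a summit of the 1959 highest of replicate 2 within 100 bp, and the same number held in the other direction. Summits placed at random on the same chromosomes gave a mean of 0.427% over 100 draws, with a highest value of 0.919%. The peaks beside epg-9 and lgg-2 ranked 1 and 2 in replicate 1 and 1 and 6 in replicate 2. Over whole lists, 47.5% of replicate 1 peaks were matched in replicate 2 and 18.5% of replicate 2 peaks in replicate 1, and these shares also depend on the unequal list lengths. Across 5560 pairs of matched peaks the signals correlated with a Spearman's rho of 0.69 (bootstrap interval 0.67 to 0.71) and a Pearson's r of 0.79 on the log2 scale. These are correlations across peaks, which are not independent replicates. Of the optimal peaks, 95.7% had a summit in the replicate 1 list and 99.7% in that of replicate 2. Among each replicate's 1959 highest peaks, the shares were 78.7% and 87.5%. The optimal peaks come from both replicates' alignments together, so these shares are not an independent measure of agreement.

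**Figure D1:**
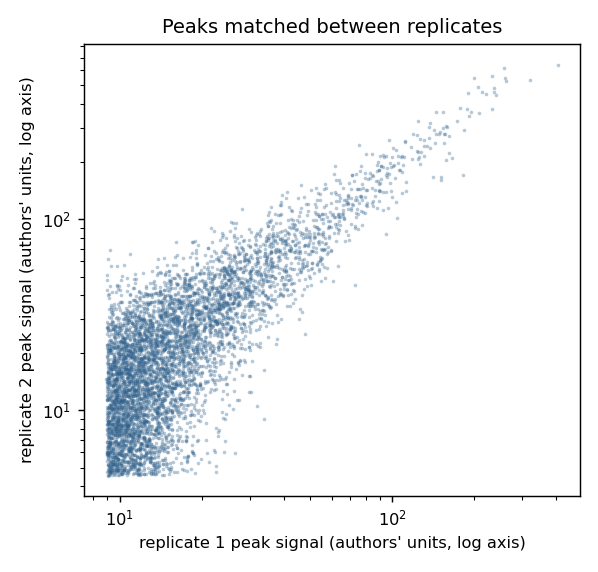
Signal of 5560 peaks matched within 100 bp between replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, 1 point per pair. The points spread widely at low signal and narrow at high signal, with a Spearman's rho of 0.69 across peaks.

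Peak centres were rich in the E-box CACGTG, the site known for TFEB-family proteins. It lay within 50 bp of 428 of 1959 summits, 21.8% (exact 95% interval 20 to 23.7%), against 2.20% of the flanking windows, a ratio of 9.95 (exact sign test, p = 2.7e-86). The longer site TCACGTGA lay at 118 summits, 6.02% (5.01 to 7.17%), against 0.179% of flanks (exact sign test, p = 8.45e-31). In each replicate's 1959 strongest peaks alone, CACGTG was at 17.6% in replicate 1 and 23% in replicate 2. Among 2080 hexamers CACGTG ranked 7 by z score and 1 by ratio. The hexamers above it by z score were GAGAGA, AGAGAG, CACACA, ACACAC, ACGTGA and AGAGAC. These ranks count occurrences, and words that overlap themselves can count several times at 1 summit. GAGAGA had 1152 occurrences at 588 summits and CACACA 753 at 350, whereas CACGTG had 458 at 428. By summits, CACACA lay at 17.9% against 4.42% of flanks, a lower share than that of CACGTG. GAGAGA lay at 30% of summits against 6.1% of flanks, and ACGCAG, of rank 9, at 20.5% against 2.45%. CGTCTC, of rank 8, lay at 445 summits, 22.7%, a higher share than that of CACGTG. Its ratio to the flanks was lower, at 5.97. CACGTG ranked 14 in the stronger part of the optimal list and 14 within 100 bp of summits.

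**Figure D2:**
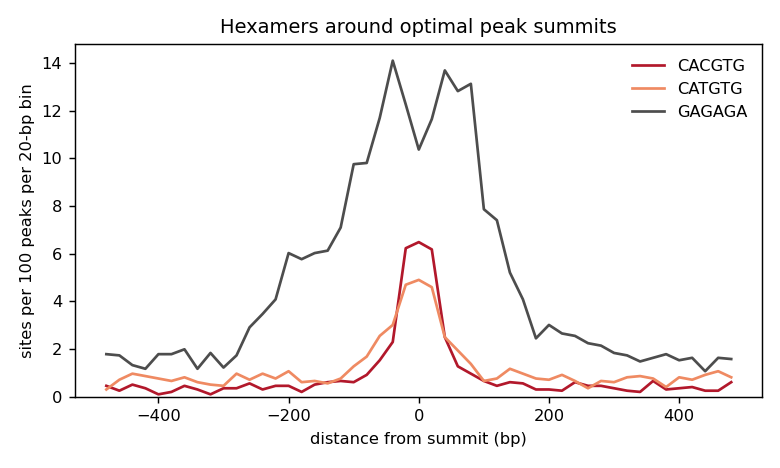
Occurrences of CACGTG, CATGTG and GAGAGA per 100 optimal peaks (y axis) by distance from the summit in 20-bp bins (x axis), counted on both strands. CACGTG and CATGTG are highest at the summit, whereas GAGAGA is raised over a broader stretch.

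The strongest peaks with TCACGTGA lay near epg-7, F09A5.3, imb-3, Y71H2AM.3 and unc-108. That nearest to imb-3, an importin beta gene, was intergenic on I, 315118 to 315386, with signal 433 and 259 bp from the start. That nearest to unc-108, a Rab2 GTPase gene, was intergenic on I, 3822746 to 3822971, with signal 281 and 39 bp from the start. The peak with F09A5.3 as its nearest gene lay 3747 bp from its start, in an intron on X, 13145189 to 13145520, with signal 505. That of Y71H2AM.3 lay 766 bp from the start on III, 2804560 to 2804780, with signal 283.

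The E-box was less frequent in the strongest peaks. CACGTG lay in 93 of the 489 peaks with the highest signal, 19%, and in 128 of the 489 with the lowest, 26.2% (Fisher's exact test, p = 0.00924). GAGAGA went the other way, at 35.2% of the strongest and 21.1% of the weakest of these peaks, a difference that was not tested. The CACGTG difference was not present in replicate 1 alone, with 18.4% of its strongest and 17.2% of its weakest peaks (Fisher's exact test, p = 0.676), and was larger in replicate 2 alone, with 18.4% and 29.0% (p = 0.00012). Within 25 bp of the summit it did not pass Fisher's exact test (p = 0.218), and in the stronger part of the optimal list it turned to 22.5% against 18.9% (p = 0.371).

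**Figure D3:**
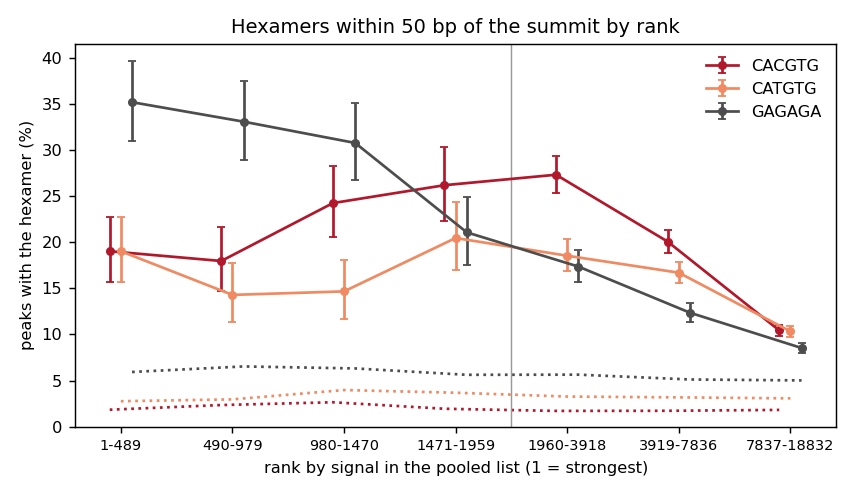
Share of peaks with CACGTG, CATGTG or GAGAGA within 50 bp of the summit (y axis, %) by rank of signal in the pooled list (x axis), with exact 95% intervals, and dotted lines for the flanks. Ranks left of the vertical line are the optimal list. CACGTG is at 19% in the strongest bin and 27.3% in the bin just below the optimal list.

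Peaks lay near gene starts and outside coding sequence. Of the 1959 summits, 892 or 45.5% (43.3 to 47.8%) were within 500 bp of a protein-coding start, against a mean of 22.5% for random positions (permutation p = 0.002, the smallest 1000 sets can give). Intergenic positions held 65.5% of summits against 36.8% of random positions and 5' UTRs 3.57% against 1.40%. Introns held 24.1% against 33.9%, coding exons 5.92% against 24.5% and 3' UTRs 0.919% against 3.38%, each with permutation p = 0.002. A peak was present at 1324 of 19973 protein-coding genes, 6.63%.

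Genes of autophagy, TORC1, endosomes and the vacuolar ATPase carried peaks more often than other genes. Of 22 lists, 8 lay above other genes and 3 below at an adjusted p under 0.05. The other genes were not matched on expression or open chromatin. Some peaks lay between neighbouring genes and counted for both, in some cases for genes of different lists. The exact test treats genes as independent, so these calls are not fully separate. Autophagy genes had peaks at 14 of 28, 50% (30.6 to 69.4%), against 6.57% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.61e-09). The strongest were lgg-2, epg-7, lgg-1 and epg-6, at signals of 847, 686, 675 and 386. The strongest epg-9 peak lies beyond this window, which holds another of signal 162. Genes of TORC1, the nutrient-sensing kinase complex, and its regulators had peaks at 7 of 18, 38.9% (exact test, adjusted p = 0.000405), led by the GTPase gene rheb-1, then aakb-2, flcn-1 and daf-15. Endosome and membrane traffic genes had them at 8 of 27, 29.6% (exact test, adjusted p = 0.000886), led by the Rab GTPase genes rab-7, rab-1, rab-5 and rab-14. The list's rab-2, annotated as unc-108, was not matched, and with it, a change made after the data were seen, the count was 9 of 28, 32.1% (exact test, adjusted p = 0.000231). The rab-7 peak is the one assigned to W03C9.5 by the nearest start. Vacuolar ATPase genes, whose proton pump acidifies lysosomes, had them at 5 of 22, 22.7% (exact test, adjusted p = 0.0285), led by vha-14, vha-8, vha-12 and vha-1. The vacuolar ATPase call was lost without replicate 1 (13.6%, exact test, adjusted p = 0.236, with 0.00568 to 1 over 11 alternatives) and, with fewer peaks, in the stronger part of the optimal list (adjusted p = 0.0909), where the odds ratio was 4.80 against 4.44 in the whole list. The endosome call was lost with a window from 500 bp upstream to 100 bp downstream (11%, exact test, adjusted p = 0.25, with 0.000231 to 0.813 over the alternatives).

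Genes of cytosolic ribosomal proteins, the respiratory chain, chaperones and the proteasome also carried peaks more often than other genes. Cytosolic ribosomal protein genes had peaks at 41 of 78, 52.6% (exact interval 40.9 to 64%; Fisher's exact test, adjusted p = 6.52e-27), led by rpl-15, rpl-14, rps-1 and rpl-3 at signals of 249, 241, 224 and 169. Respiratory chain genes had them at 12 of 34, 35.3% (exact test, adjusted p = 5.26e-06), led by cox-5A, ucr-2.1, atp-1 and sdha-1. Chaperone genes had them at 7 of 21, 33.3% (exact test, adjusted p = 0.000886), led by hsp-6, hsp-3, dnj-13 and hsp-60. Proteasome genes had them at 7 of 31, 22.6% (exact test, adjusted p = 0.0087), led by rpn-13, rpn-9, rpn-3 and rpt-2. With only peaks that hold CACGTG, the autophagy list alone stayed above other genes at an adjusted p under 0.05. It was at 21.4% against 1.09% of other genes (exact test, adjusted p = 1.22e-05, with 6.91e-12 to 0.00106 over 11 alternatives). The ribosomal list was at 3 of 78, 3.85% against 1.11% (exact test, adjusted p = 0.312, with 1.14e-27 to 0.312). The endosome list was at 1 of 27, 3.70% against 1.11% (exact test, adjusted p = 0.813). Fewer peaks entered this setting, and the vacuolar ATPase, TORC1, respiratory chain, chaperone and proteasome lists had none. With only peaks that hold neither CACGTG nor CATGTG, a setting chosen after the data were seen, 8 lists were above other genes at that threshold. Autophagy was among them at 7 of 28, 25% against 4.79% of other genes (exact test, adjusted p = 0.00106). With each peak given only to the gene with the nearest start, the endosome, vacuolar ATPase, proteasome and chaperone calls were lost, at an exact test's adjusted p of 0.0795, 0.288, 0.0688 and 0.101. Their odds ratios were then 3.25, 2.39, 3.40 and 3.42, against 6.17, 4.44, 4.33 and 7.32 by the main definition. The proteasome call was also lost in the stronger part of the optimal list (odds ratio 2.26, exact test, adjusted p = 0.522). Over the alternatives the adjusted p of the exact test ranged from 0.00102 to 1 for the proteasome and from 0.000209 to 1 for chaperones. Against random lists matched on upstream intergenic length, the unadjusted permutation p of the 11 lists that passed was at most 0.038, that of the vacuolar ATPase. This p was not adjusted over the lists, so it is not comparable with the adjusted p of the exact test.

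Lysosomal hydrolase and membrane protein genes did not pass the test, with peaks at 2 of 46, scav-3 and lmp-1 (4.35%, exact test, adjusted p = 0.939), and none of 8 lysosomal lipase genes had a peak (upper bound 36.9%, adjusted p = 1). The E-box factor genes mdl-1, mml-1 and hlh-11 had peaks, 3 of 14 (21.4%, exact test, adjusted p = 0.112), and this list passed in replicate 1 alone at 28.6% (adjusted p = 0.0289, with 0.0289 to 0.687 over 11 alternatives) and in the stronger part of the optimal list at 21.4% (adjusted p = 0.0348). Glycolysis genes had them at 3 of 19, hxk-3, pyk-1 and gpd-2 (exact test, adjusted p = 0.216), and passed with a window from 2000 bp upstream to 500 bp downstream at 26.3% (adjusted p = 0.0452, with 0.0452 to 1 over 11 alternatives). Histone genes had them at 8 of 72, led by his-72, his-31, his-32 and his-67 (exact test, adjusted p = 0.23). These histone genes shared 5 peaks among them, and his-31 and his-32 had the same peak.

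Large families with restricted expression carried few peaks. Chemoreceptor genes had them at 7 of 1309, 0.535% (exact test, adjusted p = 4.47e-29), led by srh-2, sre-23, srh-89 and sre-1. Collagen genes had them at 2 of 174, col-38 and col-185 (1.15%, exact test, adjusted p = 0.00296), and antimicrobial effector genes at 1 of 93, fipr-17 (1.08%, adjusted p = 0.042). The antimicrobial call was lost in 6 of 11 alternatives, among them the stronger part of the optimal list (0%, exact test, adjusted p = 0.153, with 0.00614 to 1 over all). The collagen call was lost in that part of the list, at 0.575% against 3.64% of other genes (exact test, adjusted p = 0.056, with 0.000706 to 0.813 over all). In the whole list the shares were 1.15% and 6.68%. The call was also lost with the nearest gene only (exact test, adjusted p = 0.0795). Lists of cell type markers did not pass the test. Peaks lay at 4 of 36 body wall muscle genes, unc-60, unc-112, act-4 and pat-3 (exact test, adjusted p = 0.41), and 0 of 32 intestine genes (upper bound 10.9%, adjusted p = 0.397). They lay at 2 of 31 epidermis genes, vab-10 and ajm-1 (exact test, adjusted p = 1), and 2 of 35 neuron genes, syd-2 and snb-1 (adjusted p = 1). They lay at 1 of 22 pharynx genes, tbx-2 (exact test, adjusted p = 1), and 1 of 34 germline genes, gld-2 (adjusted p = 0.939).

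**Figure D4:**
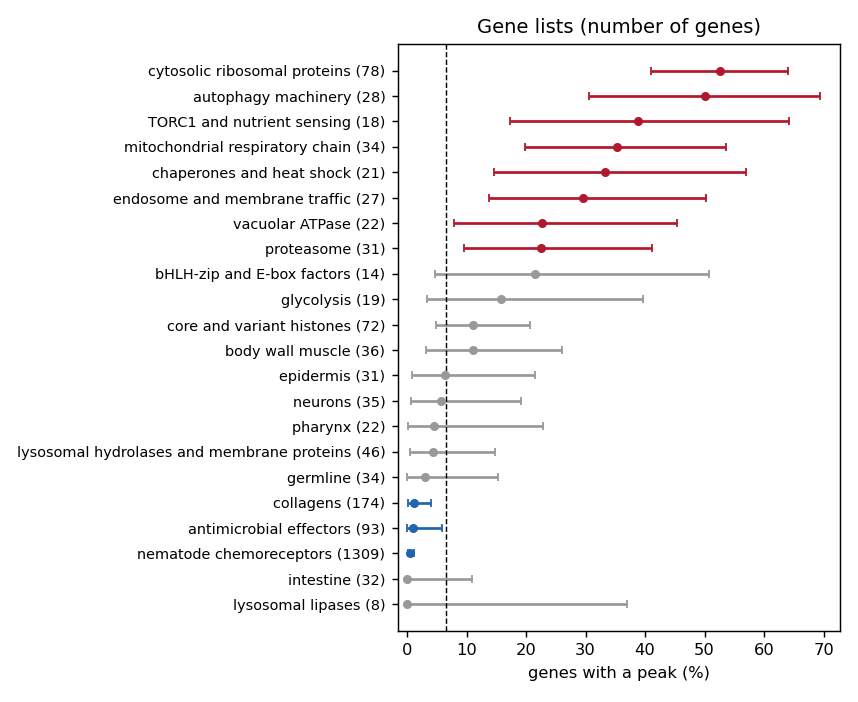
Share of genes with a peak (x axis, %) for each gene list, with its number of genes in brackets and exact 95% intervals. Red lists lie above and blue lists below other genes at an adjusted p under 0.05, grey lists do not pass, and the dashed line is the share of all protein-coding genes, 6.63%.

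Peaks were denser on the X chromosome and in the centres of the autosomes. X held 418 of 1959 peaks, 21.3% (19.5 to 23.2%), against 17.7% of the nuclear genome length (exact binomial test, p = 3.31e-05), which is 23.6 peaks per Mb against 18.7 on autosomes. Among autosomes, III had 25.6 peaks per Mb and V 12.1. The central part that makes up 50% of each autosome's length held 917 of 1541 autosomal peaks, 59.5% (57.0 to 62.0%; exact binomial test, p = 8.61e-14), and 55.7% of autosomal protein-coding gene starts. The difference from the gene starts was not tested.

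No optimal peak lay within 20000 bp of hlh-30, the tagged gene (IV, 4014793 to 4034951), or of unc-119, the marker gene of the strain (III, 10902641 to 10908935). Around hlh-30, replicate 1 had 2 summits in this window and replicate 2 had 4, with none inside the gene, and the strongest had rank 5998 and 2412. Around unc-119 there were 5 and 23 summits, of which 2 and 5 lay inside the gene, and the strongest had rank 2357 and 5547.

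**Figure D5:**
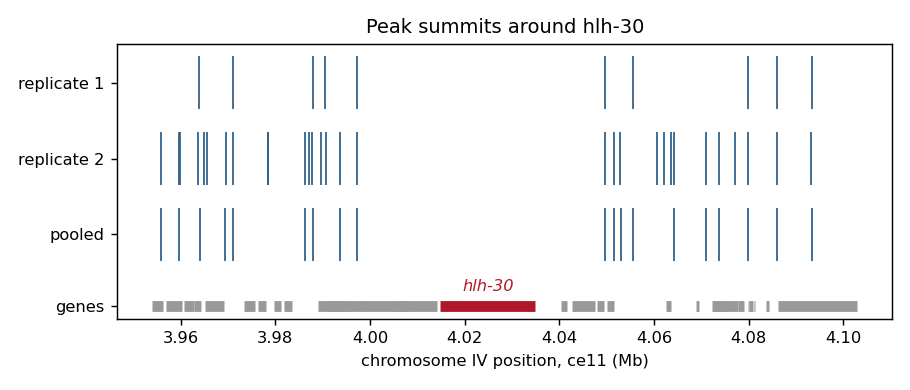
Peak summits (vertical lines) of replicate 1, replicate 2 and the pooled list along chromosome IV in ce11 (x axis, Mb) with protein-coding genes as blocks and hlh-30 in red. No summit of these lists lies between 3997224 and 4049660.

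The ce10 and ce11 lists differed little in length. The optimal list held 1978 peaks in ce10 and 1959 in ce11, replicate 1 held 11786 and 11695, the pooled list 19288 and 18832, and replicate 2 held 30000 in both. The number of optimal peaks per chromosome differed by at most 2.01%.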

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

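The share of CACGTG was also read below the optimal list, in pooled peaks that no comparison of the report used. The 1959 pooled peaks ranked just below the IDR threshold held CACGTG within 50 bp of the summit in 27.3%, against 1.71% of their flanks (exact sign test, p = 3.23e-124), and this was chosen after the data were seen. The share was lower further down, at 20.1% for ranks 3919 to 7836 and 10.4% for ranks 7837 to 18832.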

How the results depend on the processing

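Of 77 alternative values for the main results, 58 were taken as kept. These kept their direction and side of the threshold, stayed within their error or, for ranks and counts of lists, stayed close to the main value. Thus 7 or 9 lists above other genes were taken as kept against 8, although single calls changed. Values for the enrichment of CACGTG and TCACGTGA over the flanks, gene starts, the X chromosome and autosome centres were kept in every alternative run. The share of matched peaks was 47.5% with all peaks, 72.7% with the stronger part of each list, 59.0% within 50 bp, 69.7% within 200 bp and 60.4% by overlap of intervals, and 36.2% for all of replicate 1 against as many of replicate 2, chosen after the data were seen. Spearman's rho was 0.668 among optimal peaks and 0.748 within 50 bp. The rank of CACGTG was 14 in the stronger part of the optimal list, 14 within 100 bp, and from 6 to 11 with a replicate left out. CACGTG in the strongest minus weakest peaks was -3.07 percentage points within 25 bp, 3.69 in the stronger part of the list, and from -10.6 to 1.23 with a replicate left out. Lists above other genes at an adjusted p under 0.05 numbered 4 with the nearest gene only and 1 with CACGTG peaks only. Lists below at that threshold numbered 1 in the stronger part of the list, 1 with the nearest gene only and 1 with CACGTG peaks only. Fewer peaks entered the stricter and CACGTG settings, and otherwise the cause was not tested. Single lists kept their call, or stayed without a call, in 215 of 242 alternatives. The gene list alternatives without E-box peaks, without peaks near tRNA genes and with older names matched, and CATGTG in place of CACGTG, were also chosen after the data were seen. The ce10 alternative for autosome centres was not run, since ce10 chromosome lengths are not used here. No paired analysis was possible because the series has a single group. Read depth is unknown, so it is not known how far it limits the lists.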

Other observations

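The tests of CATGTG, of peaks at noncoding genes, of E-box content at autophagy and ribosomal protein genes, of shared summits as the whole cause of the ribosomal peaks, of gaps and of long genes in this part were chosen after the result, or a closely related value, had been seen. Peaks also gathered at small noncoding RNA genes. Summits within 200 bp of a tRNA gene numbered 103, 5.26% (exact 95% interval 4.31 to 6.34%), against a mean of 0.249% for random positions (permutation p = 0.002, the smallest possible). Counted separately among each replicate's own 1959 strongest peaks, 107 summits of replicate 1 and 87 of replicate 2 lay within 200 bp of a tRNA gene. For snoRNA genes, which guide modification of ribosomal RNA, 57 summits or 2.91% lay within 200 bp against 0.141%, and for snRNA genes of the spliceosome 12 or 0.613% against 0.0484%, both with permutation p = 0.002. For piRNA genes the share was below that of random positions, 0.868% against 2.86% (permutation p = 0.002). Of the tRNA peaks 35% held CACGTG or CATGTG, and of the other peaks 37.4%, a difference that was not tested.

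The genes dct-1, F07H5.13, C30E1.4 and F09A5.3 were nearest to the 4 of the 25 strongest peaks with no start within 2000 bp, at 2625, 2955, 5856 and 3747 bp, and all but F09A5.3, which has a TCACGTGA peak, are named after their values were seen. CATGTG, an E-box variant tried after the data were seen, lay at 17.1% of optimal summits against 3.34% of flanks (exact sign test, p = 8.69e-43). CACGTG or CATGTG lay at 37.3% of optimal summits.

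E-box content under the summits differed between gene lists that carried peaks. Only the strongest peak of each gene was counted for its list here, and weaker peaks of the same genes were left out of the list counts. CACGTG or CATGTG lay at 8 of 14 autophagy peaks, 57.1%, and at 4 of 40 ribosomal protein peaks, 10% (exact interval 2.79 to 23.7%), a difference with p = 0.00086 by Fisher's exact test. The autophagy share was not tested against the 37.3% of all optimal peaks. The ribosomal share did not pass an exact sign test against the 6.25% of the same peaks' flanks (p = 1) and was below the 37.8% of the other optimal peaks (Fisher's exact test, p = 0.000183). The counts were 0 of 12 at respiratory chain genes, 0 of 7 at chaperone genes, 0 of 5 at vacuolar ATPase genes, 1 of 8 at endosome genes, 2 of 7 at proteasome genes and 3 of 7 at TORC1 genes, and none of these was tested.

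Some ribosomal protein peaks may belong to a neighbouring gene, since the ribosomal protein gene's own start was the nearest for 61.0% of the 41 genes, between the bounds set for that test. With each peak given only to the gene with the nearest start, 25 of 78 ribosomal protein genes, 32.1%, still had a peak, against 6.90% of other genes (Fisher's exact test, adjusted p = 3.66e-10), which argues against shared summits as the whole cause. Over 11 alternatives the adjusted p of the exact test ranged from 1.14e-27 to 0.312. Signal that open, highly transcribed promoters give with any antibody stays open as untested, here and for the other lists above other genes. No biological explanation was tested.

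The lower share of CACGTG in the strongest peaks may have several causes. Among peaks with none of GAGAGA, CGTCTC and ACGCAG the strongest peaks were still lower, by -11.5 percentage points (22.2% of 216 strongest against 33.8% of 308 weakest peaks, Fisher's exact test, p = 0.00454), which argues against dilution by these elements as the whole cause. Within 100 bp of the summit the difference was -6.34 percentage points (Fisher's exact test, p = 0.03), which argues against less exact summits. GC content within 50 bp of the summit, 50.8% in the strongest and 46.2% in the weakest peaks, stays open as untested, and replicate 1 alone did not show the pattern. No biological explanation was tested.

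The stretch without summits around the tagged hlh-30 gene was 52486 bp long in replicate 2 and 52445 bp in replicate 1. In replicate 2, 0.857% of protein-coding genes lay in so long a gap, and 0.419% of 954 genes of like length had as few summits within 15000 bp. So long a gap was thus rare among genes in that replicate, and so few summits were rare among genes of like length. In replicate 1, with fewer peaks, these shares were 5.87% and 8.91%. The shares place hlh-30 among other genes without a model of chance, so they do not exclude chance. Of the stretch's 31-base words, 1.59% occur more than once in the reference, which argues against repeated sequence, while the longest stretches without summits in either replicate, on V at 2336431 to 2570166 and 8812059 to 8899036, were 93.0% and 98% such words. Stretches of 72422 bp on X, 65215 and 58894 bp on IV and 53861 bp on III also held no summit in either replicate. Their share of such words is not given here. The marker gene unc-119 did not show such a lack of summits. With 15000 bp on either side it had 20 in replicate 2, against a median of 11 for genes of like length. In replicate 1 it had 5, against a median of 4. Extra copies of the hlh-30 region from the transgene, which could raise reads in any library of the strain, stay open as untested. The control was not analysed here and its strain is not known here, so the direction of such an effect cannot be told. No biological explanation was tested.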
